A study of Mus musculus with 48 samples.

How the data were processed

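The values used were the deposited log2 expression summaries of 35556 probe sets on 48 Affymetrix Mouse Gene 1.0 ST arrays. Per the submitters' processing notes these came from RMA, run with the R package oligo, whose version was not given in the sources used here. That they were log2 values was read from their range, 2.16 to 13.62, with no missing value. Array medians lay between 4.64 and 4.96. A level near or below these cannot be told from background, so a difference from such a level is a lower bound. Of the arrays, 0 pairs of arrays were identical. Per the protocol labels, cells were flow sorted after gating out CD19, TCRβ, NK1.1 and Ly6G positive cells, RNA was isolated with a column kit, and 20 ng was amplified by 2 rounds before labelling. Any filter or batch correction by the authors was not stated in the labels. The scanner's own intensity files were not used here, so background correction and probe summary were left as the authors made them.

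Groups came from the sample titles: 3 macrophage subsets (CD64+CCR2+, Tim4-negative and Tim4-positive) at 4 times (naive, and 4, 6 and 8 weeks after ID8 injection), 12 groups of 4 arrays. The labels do not say whether the arrays of a group came from separate mice, so the p-values measure the spread between these samples. With 4 arrays per group, the number of arrays limited the precision of every comparison. The titles also carried a code, different for each time and the same for all arrays of that time, whose meaning was not stated. A batch that followed this code cannot be told apart from time or tumour. Comparisons of subsets at the same time lie within a single code, and differences of tumour effects between subsets cancel an offset that all subsets share.

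Gene symbols came from the probe set table supplied with the series. Of the probe sets, 21789 were listed with 1 gene symbol, 1621 with several and 12146 with none, and the last 2 kinds were left out. A gene with more than 1 probe set, as 999 had, was represented by the probe set with the highest mean over all arrays, which left 19938 genes. Of these, 19856 were matched to a current gene record, and 0 symbols had to be updated.

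A single limma model with the 12 group means was fitted to all genes (limma 3.58.1 with statmod 1.5.0 in R 4.3.3), with 36 residual degrees of freedom and empirical Bayes variances. It gave 21 comparisons: each tumour time against naive within each subset, 8 against 4 weeks within each subset, the 3 pairs of subsets in naive mice and at 8 weeks, and the 3 differences between subsets in the change from naive to 8 weeks. Tests were two-sided. The adjusted p is Benjamini-Hochberg over all genes within a comparison, a gene passed with adjusted p under 0.05 and an absolute log2 fold change of 1 or more, and members of gene lists were counted by adjusted p alone. The SE is that of the limma estimate, and n was 4 arrays per group throughout. Comparisons of a subset's 4, 6 and 8 week arrays with naive share the naive arrays, so overlaps between them were not counted.

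The 25 gene lists held 378 genes, of which 346 were measured. They covered cholesterol efflux and LXR targets, cholesterol biosynthesis and uptake, IL-4 and STAT6 alternative activation, the interferon-gamma response, the type I interferon response, NF-kB inflammatory genes, resident large peritoneal macrophages, monocytes and small peritoneal macrophages, MHC class II and co-stimulation, cell cycle, glycolysis and hypoxia, oxidative phosphorylation and the TCA cycle, fatty acid oxidation, lipid-associated and lysosomal macrophages, pro-angiogenic and immunosuppressive mediators, and markers of B cells, T cells, NK cells, neutrophils, mast cells, eosinophils, dendritic cells, epithelium, mesothelium and fibroblasts, and erythroid cells. The lists and thresholds were set before the data were examined. The resident list holds Timd4 and the monocyte list Ccr2, which are sort markers. In comparisons of subsets these members were moved by the sort itself. Each list was tested against all other genes with camera from limma at its preset correlation of 0.01, adjusted over the 25 lists within a comparison, and again with a correlation estimated from the data. Of 525 list tests, 161 passed with the preset correlation and 28 of these held with the estimated correlation. The list p is given with the preset correlation unless the text says otherwise.

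Genes were named by a rule for 9 comparisons (8 weeks against naive, naive subset pairs, and differences of the tumour effect). The rule took the 6 largest rises and 6 largest falls past both thresholds, leaving out predicted and unnamed loci and, in comparisons of 2 groups, genes whose arrays overlapped between groups. It added up to 4 members of each list with the largest absolute log2 fold change past the adjusted p, and a set of focal genes: Timd4, Ccr2, Fcgr1, Abca1, Abcg1, Apoe, Arg1, Chil3, Retnla, Mrc1, Gata6, H2-Ab1 and Mki67. Hmgcr, Ldlr and Stat1, which were on the focal list too, and the other unmatched list genes had no probe set listed with their symbol alone and were not analysed here. Genes named for the other 12 comparisons were chosen after their values were seen.

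The code was tested on simulated data made from the mean and spread of each gene, with independent noise and the changed genes drawn from all genes. Of genes given a log2 change of 0.50, 41 of 67 passed the adjusted p and 0 passed both thresholds. At a change of 1 these were 63 and 35 of 67, and at a change of 2 they were 66 and 66 of 66. Among unchanged genes 11 passed the adjusted p and 1 passed both thresholds. The list that had been raised was recovered, and 1 other list passed.

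Alternatives to this fit were quantile normalization, shifting arrays to a common median, leaving out 8033 dim genes, averaging probe sets, a trended and robust prior, array weights, a fit to only the groups compared, 3 ways of using the replicate number as a block, and leaving out each array in turn. After the values had been seen, 3 more were added: leaving out 6 naive arrays with Y-linked transcripts, a term for those transcripts, and leaving out the naive arrays numbered 1. The test for exchanged naive and tumour arrays replaced 2 earlier forms. The first asked for Y-linked signal in tumour arrays, which the definition of the 6 arrays had already settled. The second used genes called in the same subset, which had been chosen on the remaining naive arrays, and it left the exchange open. The bound of the last form, and its division into 4 weeks and 6 or 8 weeks, were set after its values were seen.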

Results

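Peritoneal macrophages of C57Bl/6 mice were compared in 12 groups of 4 arrays. The cells were sorted as CD64+CCR2+, Tim4-negative or Tim4-positive, and were taken from naive mice or 4, 6 or 8 weeks after ID8 cells, spontaneously transformed mouse ovarian surface epithelium, had been placed in the peritoneal cavity. Tim4 (Timd4) is a phosphatidylserine receptor of long-lived resident peritoneal macrophages, and Ccr2 is the chemokine receptor that brings monocytes into tissue. The question behind the series is how tumour growth changes these cells, in particular their cholesterol export and their response to IL-4. Across genes, which are not independent replicates, the correlation between arrays of a group ranged from 0.96 to 0.993, and the lowest mean, 0.965, belonged to array 1 of the naive CD64+CCR2+ group. The first principal component held 29.6% of the variance and the second 9.4%.

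Transcripts of the sex chromosomes split the naive arrays. Eif2s3y, which lies on the Y chromosome, was at log2 7.34 or above in 6 naive arrays, numbers 2 and 3 of each subset, and at 3.19 or below in the other 42. Xist, the transcript that silences an X chromosome in female cells, was at 4.56 or below in those 6 and at 7.69 or above in the others. All 36 arrays from tumour-bearing mice lacked the Y-linked signal. Counts that involve naive arrays are therefore also given without these 6 arrays, and without the naive arrays numbered 1.

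**Figure D1:**
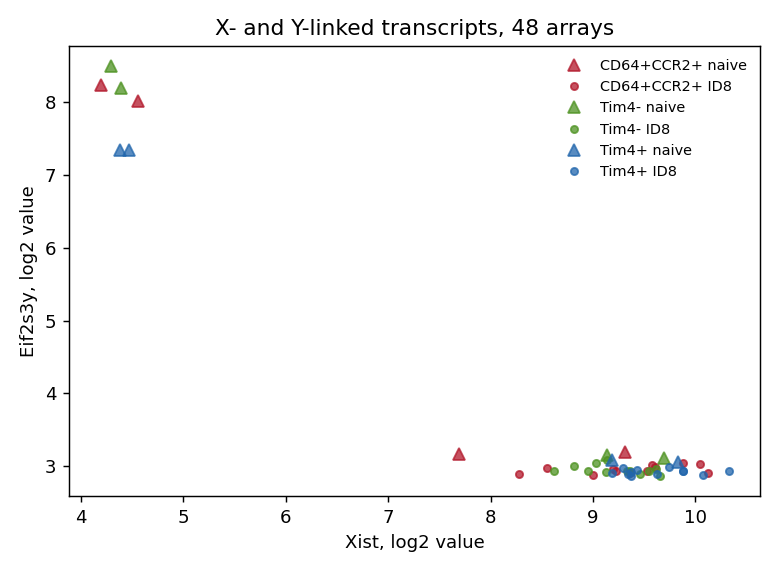
Log2 level of Eif2s3y (vertical) against Xist (horizontal) for each of the 48 arrays, coloured by subset, with triangles for naive arrays and circles for arrays after ID8 injection. The 6 naive arrays with Eif2s3y at 7.34 or above stand apart from the other 42.

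In naive mice the Tim4-positive and Tim4-negative cells differed in the sort marker Timd4 and in the monocyte receptor Ccr2. Timd4 was higher in Tim4-positive cells by log2 6.66 (SE 0.32, adjusted p = 2.84e-18), at 11.30 (SD 0.04, n = 4) against 4.64 (SD 0.11, n = 4), a level no higher than the array medians (4.64 to 4.96), so the difference is a lower bound. Ccr2 was lower by -4.01 (SE 0.31, adjusted p = 1.6e-11). Apoc1, an apolipoprotein of lipid-handling macrophages, was higher (3.16, SE 0.58), as were Tcim (2.06, SE 0.43) and the hypoxia factor Epas1 (1.55, SE 0.26). Chil3 and Retnla, secreted products of IL-4 stimulated macrophages, were lower (-3.80, SE 0.89 and -0.90, SE 0.23), and so were Cenpw (-2.52, SE 0.40), Tmem154 (-1.89, SE 0.31) and Ifnz (-1.88, SE 0.30). Chil3 averaged 4.72 in Tim4-positive cells, within the array medians, so its difference is a lower bound. The antigen presentation genes Cd74 (-1.93, SE 0.40) and H2-Ab1 (-1.87, SE 0.39) were lower as well, whereas Gata6, the factor that holds the resident identity, did not pass (-0.06).

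By gene list, Tim4-positive cells had lower cell cycle genes (median log2 -0.80; adjusted p = 3.74e-18, and 0.121 with an estimated correlation). Of 29 cell cycle genes, 3 were lower, among them Ccna2 (-1.71, SE 0.42) and Rrm2 (-1.45, SE 0.38), and 19 when adjusted over the list alone. MHC class II genes were lower (adjusted p = 4.92e-05, and 0.121 with an estimated correlation), with 2 of 11 members lower and 4 adjusted over the list alone. Oxidative phosphorylation genes (3.67e-06, and 0.304 estimated) and monocyte genes (0.000266, and 0.121 estimated) were lower too, while resident macrophage genes were higher (0.000266, and 0.433 estimated), Tgfb2 among them (1.21, SE 0.30). The sort marker Timd4 is itself a member of the resident list. The IL-4 list did not differ as a whole (adjusted p = 0.286; median 0.01, mean -0.22). Past both thresholds stood 56 genes, 25 higher and 31 lower (45 without the arrays with Y-linked transcripts, 53 without the naive arrays numbered 1). The count was 36 with array weights, 20 with a fit limited to the groups compared and, with arrays shifted to a common median, split into 21 higher and 46 lower. This fit made no use of the replicate number, and with the number as a fixed block within time the count was higher, as given under the processing. Of the 19 genes named past the test, 13 lost it without the arrays with Y-linked transcripts and 8 without Tim4-negative naive array 4, Chil3 and Retnla among the latter.

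The naive CD64+CCR2+ cells differed far more from both other subsets, along the known axis from monocyte-derived to resident macrophages. Against Tim4-negative cells, Ccr2 was higher by 2.35 (SE 0.31, adjusted p = 1.4e-06) and the mannose receptor Mrc1 by 2.78 (SE 0.32, adjusted p = 8.28e-08). Fcrls (4.79, SE 0.39), the adhesion receptor Cd226 (4.74, SE 0.33) and the lectin Clec4b1 (4.09, SE 0.38) were the highest. The resident genes Vsig4 (-5.73, SE 0.55), Ltbp1 (-4.84, SE 0.22), Tgfb2 (-4.47, SE 0.30) and Gata6 (-2.54, SE 0.25) were lower, as were the fatty acid carrier Fabp4 (-3.78, SE 0.39) and arginase, Arg1 (-2.33, SE 0.71, adjusted p = 0.0465). Timd4 was itself higher in CD64+CCR2+ than in Tim4-negative cells, by 3.42 (SE 0.32, adjusted p = 8.03e-10), at 8.05 (SD 0.91, n = 4) against 4.64, so this is a lower bound too. Fcgr1, which encodes CD64, did not pass (-0.95, adjusted p = 0.227). Naive CD64+CCR2+ array 1 had Fcgr1 at 5.07 against 7.35 to 7.89 in the other 3 arrays of its group, and without it the difference was -0.32 (adjusted p = 0.809).

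Against Tim4-positive cells the same axis was longer. Ccr2 was higher in CD64+CCR2+ cells by 6.37 (SE 0.31, adjusted p = 1.83e-18), Fcrls by 6.39 (SE 0.39), Mrc1 by 3.90 (SE 0.32) and Retnla by 1.37 (SE 0.23). Vsig4 was lower (-6.84, SE 0.55), as were Ltbp1 (-5.28, SE 0.22), Apoc1 (-4.38, SE 0.58), Timd4 (-3.24, SE 0.32), Arg1 (-3.26, SE 0.71) and the cholesterol exporter Abca1 (-0.86, SE 0.23, adjusted p = 0.0101). Fcgr1 did not pass (-0.24, and 0.39 without CD64+CCR2+ array 1).

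The lists followed these genes, and they include the sort markers, Timd4 among the resident and Ccr2 among the monocyte genes. In CD64+CCR2+ cells 12 of 17 resident genes were lower and 1 higher than in Tim4-negative cells (median -2.13, adjusted p = 8.32e-31, and 0.00013 with an estimated correlation), and 15 of 17 were lower than in Tim4-positive cells (median -2.48, adjusted p = 2.45e-34, and 5.05e-05 estimated). Monocyte genes were higher, 7 of 15 against Tim4-negative cells (9.8e-15, and 0.00013 estimated) and 11 of 15 against Tim4-positive cells (5.09e-18, and 4.66e-05 estimated). MHC class II genes were higher, with 6 members up and 1 down in either comparison (4.62e-06 and 3.64e-10; 0.0462 and 0.00433 estimated). H2-Eb1 was higher by 2.74 (SE 0.42) and 4.30 (SE 0.42). The IL-4 list leaned the same way (0.00136 and 0.000229; 0.0462 and 0.0221 estimated) with 8 of 24 members higher and 3 lower against Tim4-negative cells, and 9 and 3 against Tim4-positive cells. Against Tim4-positive cells alone, cell cycle genes were higher too (4.05e-07, and 0.474 estimated; 3 of 29 members, 11 adjusted over the list alone), while the efflux list did not differ (0.798; median 0.07, mean -0.22).

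Past both thresholds, 364 genes separated naive CD64+CCR2+ from Tim4-negative cells (161 higher, 203 lower) and 548 separated them from Tim4-positive cells (299 higher, 249 lower). With arrays shifted to a common median the latter split was 408 higher and 223 lower. Without the arrays with Y-linked transcripts the counts were 348 and 627, and without the naive arrays numbered 1 they were 266 and 494. With a fit limited to the groups compared the former was 232. Of the 50 and 60 genes named past the test, 13 and 13 lost it without the arrays with Y-linked transcripts, and 15 and 12 without the naive arrays numbered 1.

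**Figure D2:**
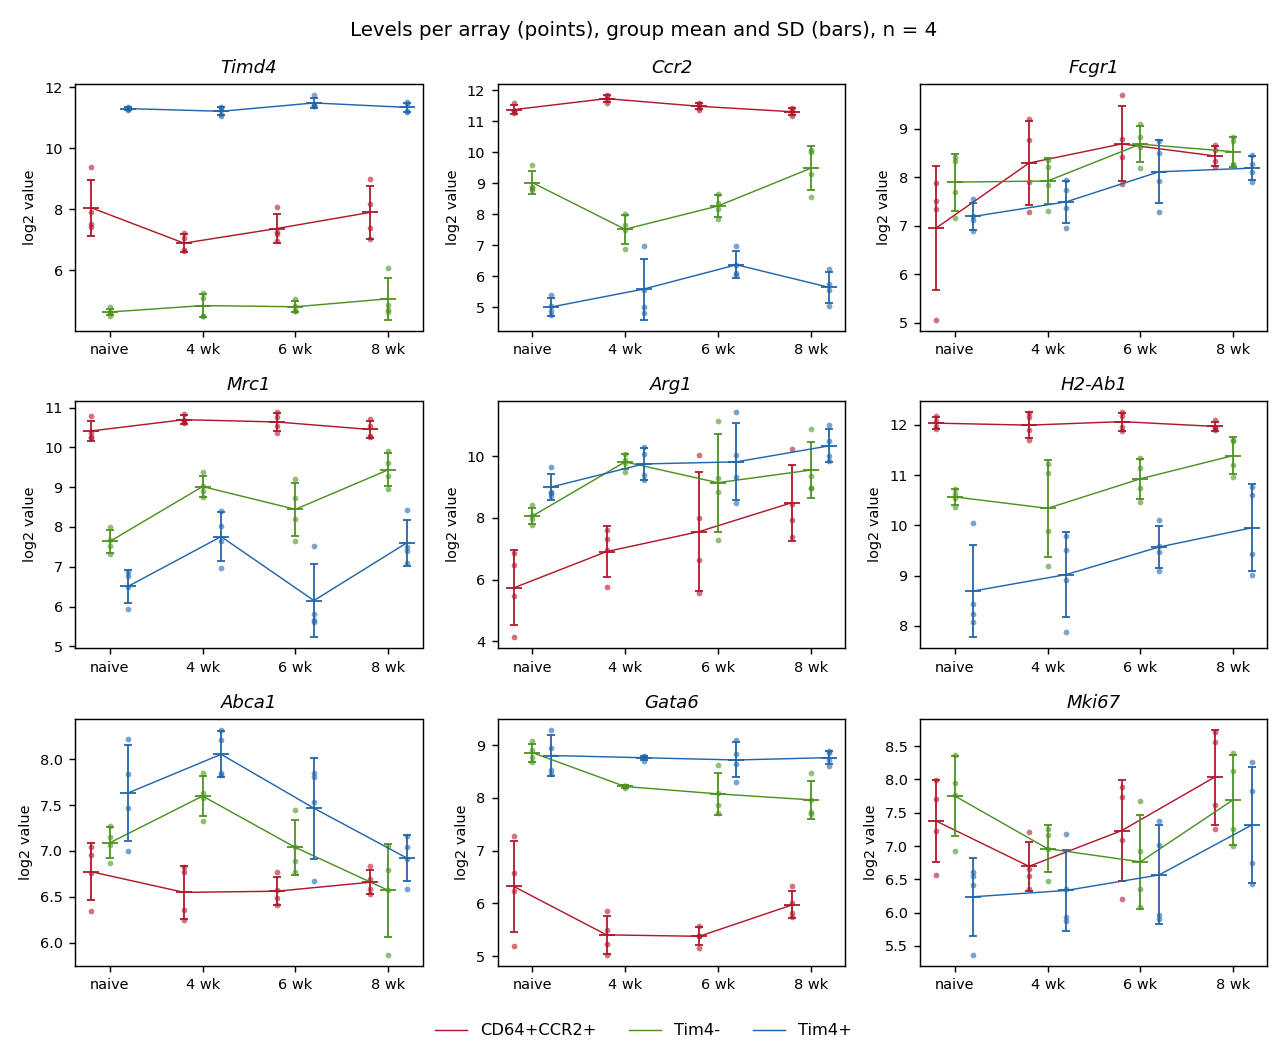
Log2 level (vertical) of 9 focal genes in naive mice and 4, 6 and 8 weeks after ID8 injection (horizontal), with points for arrays, bars for the mean and SD of 4 arrays, and lines joining the means of each subset. In naive mice Timd4 averages 11.30 in Tim4-positive and 4.64 in Tim4-negative cells, and Mrc1 in Tim4-negative cells goes from 7.64 to 9.43 at 8 weeks.

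At 4 weeks few genes had changed from naive, and those named here were chosen after their values were seen. In CD64+CCR2+ cells the interferon-inducible Ms4a4c rose (2.93, SE 0.41, adjusted p = 6.63e-05), with the pyrin gene Mefv (1.46, SE 0.18), Gdf3 (1.53, SE 0.20) and Cd63 (1.52, SE 0.35), a tetraspanin of late endosomes. The lectin Cd209f (-2.44, SE 0.25, adjusted p = 1.35e-07) and Icam2 (-1.49, SE 0.35) fell. Monocyte genes rose as a list in this subset (median 0.71; adjusted p = 8.52e-08, and 0.0153 with an estimated correlation), with 1 of 15 members past the test and 6 adjusted over the list alone. The IL-4 list rose as well (median 0.23; 9.09e-05, and 0.0221 estimated), though 0 of 24 members passed by limma and 1 adjusted over the list alone. Sterol genes rose as a list (median 0.46; 1.18e-06, and 0.522 estimated) with 0 of 20 members past the test.

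The CD64+CCR2+ count at 4 weeks was 25 (18 higher, 7 lower), and it hung on naive array 1. It was 90 without that array, 12 without naive array 2, and 16 and 15 without arrays 1 and 2 of the 4 week group. Quantile normalization gave 16 (9 higher, 7 lower), array weights 50, a common median a split of 20 and 4, and a fit limited to the groups compared 2. Without the arrays with Y-linked transcripts it was 18 and without the naive arrays numbered 1 it was 98. Of 35 ways to split these 8 arrays into 4 and 4, 6 gave as many genes, up to 184, so chance cannot be excluded.

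In Tim4-negative cells 5 genes passed at 4 weeks: the scavenger receptor gene Marco rose (1.66, SE 0.31, adjusted p = 0.018), and Emb (-2.19, SE 0.35), Ccr2 (-1.51, SE 0.31), Cav1 (-1.42, SE 0.27) and Cxcl12 (-1.26, SE 0.26) fell. The efflux list rose (median 0.26; adjusted p = 0.00519, and 0.17 with an estimated correlation) with 1 of 16 members up, and cell cycle genes fell as a list (median -0.50; 4.53e-05, and 0.776 estimated) with 0 members past the test by limma. In Tim4-positive cells Slc28a2 (1.28, SE 0.25) and Ptgr1 (1.24, SE 0.26) rose and Ier2 (-1.21, SE 0.22) fell, and no other gene passed. Oxidative phosphorylation genes rose as a list there (median 0.21; adjusted p = 9.96e-05), a call lost with an estimated correlation.

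These small counts moved with single arrays. The Tim4-negative count of 5 (1 higher, 4 lower) was 1, 2 and 0 without 4 week arrays 2, 3 and 4, and 10, 2 and 2 without naive arrays 1, 2 and 3. It was 8 without the arrays with Y-linked transcripts, 16 without the naive arrays numbered 1, 19 with array weights, 2 with a fit limited to the groups compared, and 3 (1 higher, 2 lower) with a common median. The Tim4-positive count of 3 (2 higher, 1 lower) was 5 and 6 without 4 week arrays 1 and 4, and 11, 6, 6 and 5 without naive arrays 1, 2, 3 and 4. It was 16 without the arrays with Y-linked transcripts, 13 with a term for them, 18 without the naive arrays numbered 1, 6 with a trended and robust prior, and 0 with a fit limited to the groups compared. Quantile normalization split it into 2 higher and 2 lower.

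**Figure D3:**
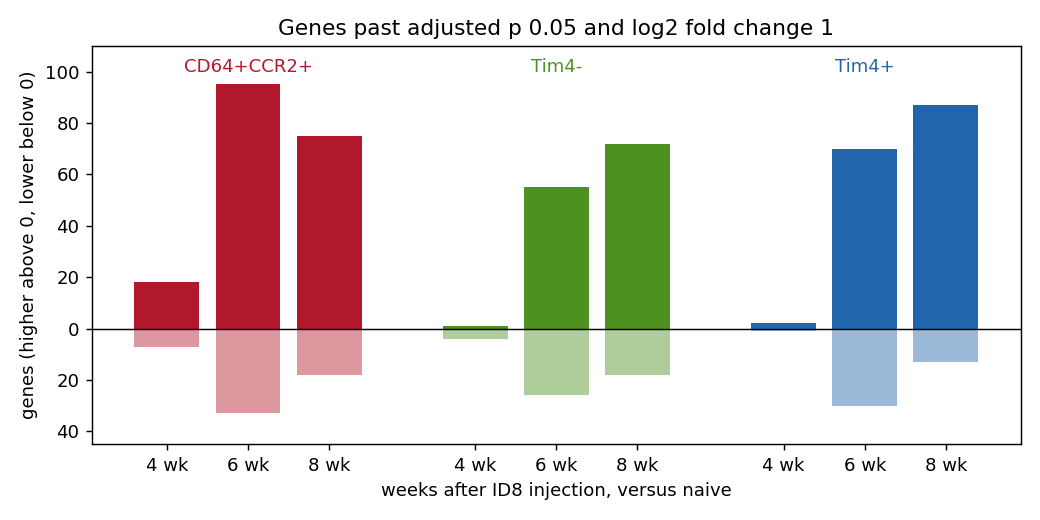
Number of genes past both thresholds at 4, 6 and 8 weeks against naive (horizontal) in each subset, with rises drawn above 0 and falls in paler bars below 0. From 4 to 8 weeks the total goes from 25 to 93 in CD64+CCR2+, 5 to 90 in Tim4-negative and 3 to 100 in Tim4-positive cells.

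At 6 weeks single interferon-inducible genes had risen in all 3 subsets (genes chosen after their values were seen), while the calls of the interferon lists were lost with an estimated correlation. Such genes arm macrophages against intracellular microbes and respond to interferon from T and NK cells. Iigp1, an immunity-related GTPase, rose by 2.91 (SE 0.79) in CD64+CCR2+, 3.18 (SE 0.79) in Tim4-negative and 2.74 (SE 0.79) in Tim4-positive cells, and Irgm1 by 1.67, 1.80 and 2.08 (SE 0.42 each). In the same order, the interferon-gamma list rose by a median of 0.62, 1.00 and 0.93 (adjusted p = 3.72e-08, 1.3e-13 and 6.22e-12). Of its 16 members 2, 6 and 7 passed, and 9, 12 and 13 adjusted over the list alone. The type I interferon list rose by 0.56, 0.73 and 0.75 (3.95e-09, 6.2e-14 and 1.92e-12), with 0, 2 and 5 of 19 members past the test by limma and 5, 8 and 13 adjusted over the list alone. With an estimated correlation none of these calls held (adjusted p = 0.195, 0.0815 and 0.134, then 0.195, 0.14 and 0.134). The checkpoint ligand Cd274 rose in Tim4-negative (1.28, SE 0.31) and Tim4-positive cells (1.48, SE 0.31), and Gbp5 in both (2.11, SE 0.50 and 2.10, SE 0.50).

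Other genes that changed at 6 weeks included cytokine, resident macrophage and lipid genes. In CD64+CCR2+ cells the cytokine Il1b rose (2.17, SE 0.51) with Cd63 (2.73, SE 0.35) and Idi1 (1.94), an enzyme of sterol synthesis, and the resident genes Alox15 (-2.84, SE 0.52), Prg4 (-2.71, SE 0.53), Icam2 (-2.23, SE 0.35) and Gata6 (-0.94, SE 0.25) fell. There 6 of 17 resident genes fell (median -0.58; adjusted p = 0.000146, and 0.195 with an estimated correlation). The transglutaminase Tgm2, which IL-4 induces, rose in all 3 subsets (2.01, 2.71 and 2.47), and lipoprotein lipase, Lpl, fell in Tim4-negative (-2.06, SE 0.24) and Tim4-positive cells (-1.83, SE 0.24). In Tim4-positive cells Ccr2 rose (1.36, SE 0.31), Retnla (-1.17, SE 0.23) and F13a1 (-2.70) fell, and 4 of 21 oxidative phosphorylation genes rose (9.55e-07, and 0.262 estimated). B cell markers were higher as a list in CD64+CCR2+ (median 0.47; 0.00023, and 0.195 estimated) and Tim4-negative cells (median 0.57; 0.000109, and 0.153 estimated), Ms4a1 rising by 1.74 (SE 0.46) in the former. NF-kB genes rose as a list in the same 2 subsets (0.00225 and 0.00376; 0.195 and 0.185 estimated), and the pro-angiogenic list in Tim4-negative cells (0.0186, and 0.153 estimated).

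Past both thresholds at 6 weeks were 128 genes in CD64+CCR2+ cells (95 higher, 33 lower), 81 in Tim4-negative cells (55 and 26) and 100 in Tim4-positive cells (70 and 30, or 83 and 15 with a common median). Without the arrays with Y-linked transcripts these were 119, 71 and 116, and without the naive arrays numbered 1 they were 162, 73 and 115. A fit limited to the groups compared gave 28, 3 and 5. The Tim4-negative count was 52 without naive array 3. The Tim4-positive count was 62, 168 and 48 without 6 week arrays 1, 2 and 4, and 65 without naive array 4.

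At 8 weeks CD64+CCR2+ cells had more Sparc, a secreted matrix protein and a marker of mesothelium and fibroblasts. Beside it rose the mesothelial markers Upk1b (1.99) and Wt1 (1.01) and the matrix gene Dcn (1.32). Sparc rose from 4.27 (SD 0.28) to 7.14 (SD 0.92), by 2.87 (SE 0.49, adjusted p = 0.000783), a lower bound since the naive level lay below the array medians. The endosomal Cd63 (2.49, SE 0.35), the scavenger receptor Marco (2.23, SE 0.31) and the immune receptors Cd200r4 (2.39, SE 0.39) and Lilra5 (2.18, SE 0.31) rose. Arg1, which IL-4 induces and which takes arginine away from T cells, rose from 5.73 (SD 1.21) to 8.49 (SD 1.23), by 2.76 (SE 0.71, adjusted p = 0.0353), and Vsig4 by 1.99 (SE 0.55, adjusted p = 0.049). The progesterone-metabolizing Akr1c18 (-1.88, SE 0.28), the histone gene H1f2 (-1.93, SE 0.42), the early response gene Fos (-1.59, SE 0.31) and Lpl (-1.17, SE 0.24) fell. Fcgr1 (1.49, SE 0.42, adjusted p = 0.0553), Abca1 (-0.12, SE 0.23, adjusted p = 0.811), Mrc1 (0.04), Retnla (-0.07), Chil3 (0.24), Gata6 (-0.35), H2-Ab1 (-0.06) and Timd4 (-0.15) did not pass. The Fcgr1 change was 0.86 without naive array 1, where Fcgr1 was low, and passed without naive array 3 (adjusted p = 0.0488) or 4 (adjusted p = 0.0206).

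Sterol synthesis genes, which cells turn on when cholesterol in their membranes runs low, rose in this subset, with 3 of 20 past the test: Idi1 (2.10, SE 0.45), Sqle (1.46, SE 0.37) and Hmgcs1 (1.21, SE 0.28). Adjusted over the list alone 8 passed (median 0.43, adjusted p = 7.85e-09, and 0.308 with an estimated correlation). The 8 week array 2 stood apart, with a list median of 1.34 against at most 0.48 in the others. Cell cycle genes rose (median 0.56; 2.25e-11, and 0.308 estimated), with 2 of 29 past the test and 8 adjusted over the list alone, among them Ccne2 (adjusted p = 0.00191). Glycolysis genes rose as a list (0.00125, and 0.339 estimated) with 1 of 20 members up, P4ha1 (0.87, SE 0.18), as did the lipid-associated and lysosomal list (0.00146, and 0.119 estimated) with 2 of 20 up and 1 down. The type I interferon list rose with 0 members past the test by limma (0.0185, and 0.647 estimated), and the dendritic cell list fell (0.0182, and 0.365 estimated) with Batf3 (-0.89, SE 0.20), as did mast cell markers (0.0182, and 0.339 estimated). Within the IL-4 list, which did not change as a whole (0.416; median -0.04, mean 0.08), Arg1 and Tgm2 (1.53, SE 0.38) rose and the lectin Clec10a (-1.29, SE 0.31) fell.

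The CD64+CCR2+ count at 8 weeks was 93 (75 higher, 18 lower), 144 without the arrays with Y-linked transcripts, 143 with a term for them, 72 without the naive arrays numbered 1 and 9 with a fit limited to the groups compared. It was 59 without 8 week array 4 and 61 without naive array 1. Of the 30 genes named past the test, 13 lost it without the arrays with Y-linked transcripts, 25 with a fit limited to the groups compared, and 17 when some single array was left out, Arg1, Vsig4, Idi1, Sqle and Hmgcs1 among the last.

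In Tim4-negative cells at 8 weeks sterol, antigen presentation and interferon genes rose as lists, calls that were lost with an estimated correlation. The mesothelial and fibroblast marker Sparc rose as well. Ms4a6b (3.70, SE 0.53, adjusted p = 5.19e-05), Sparc (3.33, SE 0.49), the lipid desaturase gene Scd2 (3.21, SE 0.67), Gatm (2.50, SE 0.46), Cd226 (2.36, SE 0.33) and Tgm2 (2.33, SE 0.38) rose. Mrc1, a mannose receptor that IL-4 raises, rose from 7.64 (SD 0.29) to 9.43 (SD 0.41), by 1.80 (SE 0.32, adjusted p = 0.00109), and the fractalkine receptor Cx3cr1 by 1.58 (SE 0.25, adjusted p = 0.000192). Lpl (-1.83, SE 0.24, adjusted p = 2.02e-05), Ifnz (-1.79, SE 0.30), Cxcl12 (-1.56, SE 0.26), coagulation factor gene F5 (-1.45, SE 0.27) and Ltbp1 (-1.28, SE 0.22) fell. Arg1 (1.49, SE 0.71, adjusted p = 0.329), Abca1 (-0.52, SE 0.23, adjusted p = 0.276), Gata6 (-0.89, SE 0.25, adjusted p = 0.0569), Chil3 (-0.82), Retnla (-0.11), Ccr2 (0.46) and Timd4 (0.44) did not pass.

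Of 20 sterol genes 6 rose in these cells, Sqle (1.75, SE 0.37), Stard4 (1.32, SE 0.28), Cyp51 (1.32, SE 0.34) and Hmgcs1 (1.12, SE 0.28) among them, and 16 adjusted over the list alone (median 0.94, adjusted p = 7.65e-17, and 0.0763 with an estimated correlation). The 8 week array 2 stood apart, with a list median of 1.77 against at most 0.89 in the others. The IL-4 list rose (median 0.11; 0.0106, and 0.137 estimated) with 3 of 24 members up: Tgm2, Mrc1 and the receptor subunit Il4ra (0.62, SE 0.16). MHC class II genes rose (median 0.82; 0.000129, and 0.0837 estimated), with H2-Eb1 (1.82, SE 0.42) up, Cd86 (-0.91, SE 0.22) down, and 5 up and 1 down adjusted over the list alone. The interferon-gamma list rose (median 0.55; 8.27e-06, and 0.15 estimated) with Psmb9 (1.06, SE 0.21) and Ciita (0.94, SE 0.23), and the type I list with 0 members by limma (0.000373, and 0.399 estimated). Monocyte genes rose (0.000136, and 0.0763 estimated; 3 of 15 up). Resident genes fell (median -0.36; 0.0301, and 0.443 estimated; 2 of 17 down and 6 adjusted over the list alone), and so did mast cell markers (0.000126, and 0.0763 estimated; 2 of 8 down). Glycolysis (0.000146, and 0.15 estimated), oxidative phosphorylation (0.000353, and 0.303 estimated) and cell cycle genes (0.00575, and 0.521 estimated) rose as lists.

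The Tim4-negative count at 8 weeks was 90 (72 higher, 18 lower), 86 without the arrays with Y-linked transcripts and 100 without the naive arrays numbered 1. It was 50 without 8 week array 4, the array with the highest Timd4 of its group (6.08). Of the 37 genes named past the test, 11 lost it without the arrays with Y-linked transcripts and 17 when some single array was left out, Scd2, Sqle, Il4ra, Ciita, H2-Eb1 and Cd86 among them, while Mrc1, Tgm2, Npc1, Stard4, Lpl and Cx3cr1 kept it in every setting.

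In Tim4-positive cells at 8 weeks the largest changes lay in genes of varied function, and genes of energy metabolism rose as lists, calls that were lost with an estimated correlation. Sparc (3.11, SE 0.49), the circadian repressor Bhlhe41 (2.75, SE 0.49), the complement regulator Cd55 (2.64, SE 0.35, adjusted p = 2.17e-05), Tgm2 (2.31, SE 0.38) and Marco (2.09, SE 0.31) rose, as did Gpnmb, a glycoprotein of lipid-laden macrophages (1.37, SE 0.18, adjusted p = 2.17e-05). Lpl (-1.34, SE 0.24), the laminin gene Lama3 (-1.30, SE 0.18) and the small RNAs Rny3 (-2.53, SE 0.58) and Rmrp (-1.40, SE 0.37) fell. Timd4 (0.04), Gata6 (-0.04) and Abca1 (-0.71, SE 0.23, adjusted p = 0.0545) did not pass, nor did Ccr2 (0.63), Arg1 (1.34), Chil3 (-0.24), Retnla (-0.65, adjusted p = 0.0786) or Mki67 (1.08, adjusted p = 0.128). Chil3 averaged 4.72 in naive mice and 4.48 at 8 weeks, so neither level can be told from background. Mrc1 rose by 1.09 (SE 0.32, adjusted p = 0.0381).

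Glycolysis genes rose as a list in these cells (median 0.48; adjusted p = 1.48e-09, and 0.0837 with an estimated correlation), 5 of 20 past the test and 11 adjusted over the list alone, Pgk1 (0.96, SE 0.23) among them. So did oxidative phosphorylation genes (median 0.34; 9.11e-10, and 0.118 estimated), 3 of 21 past the test, among them Cox5a (0.72, SE 0.15) and Atp5b (0.48, SE 0.10). Of 29 cell cycle genes 1 rose, and 16 adjusted over the list alone (median 0.73; 6.29e-12, and 0.222 estimated). Of 20 sterol genes 1, Stard4 (1.08, SE 0.28), rose, and 7 adjusted over the list alone (median 0.68; 3.41e-07, and 0.319 estimated). MHC class II genes rose (0.00034, and 0.18 estimated), 4 of 11 past the test, Cd74 (1.83, SE 0.40) and H2-Ab1 (1.26, SE 0.39, adjusted p = 0.0453) among them. The interferon-gamma list (0.00138, and 0.374 estimated) and the type I list (0.0147, and 0.541 estimated) rose with 0 members past the test by limma. The monocyte list (0.0475, and 0.374 estimated) and the lipid-associated list (0.0475, and 0.319 estimated) also passed. The IL-4 list did not (0.258; median -0.03, mean 0.16), with 2 members up and 1, Cdh1 (-0.33, SE 0.07), down, nor did fatty acid oxidation (0.0778), although Acadl rose (0.80, SE 0.21).

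The Tim4-positive count at 8 weeks was 100 (87 higher, 13 lower), 149 without the arrays with Y-linked transcripts, 142 without the naive arrays numbered 1 and 41 with a fit limited to the groups compared. It was 156 and 51 without 8 week arrays 1 and 4. Of the 41 genes named past the test, 17 lost it with quantile normalization, 14 without the arrays with Y-linked transcripts, 31 with a fit limited to the groups compared and 23 without 8 week array 4, among them Mrc1, Stard4, Scd2, Cdh1, Rny3, Rmrp and H2-Ab1, and Pgk1 and Acadl lost it without some other array.

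The list of cholesterol efflux genes and other targets of LXR receptors, which respond when sterols build up, did not pass at 8 weeks. The efflux list had adjusted p = 0.547 in CD64+CCR2+, 0.504 in Tim4-negative and 0.474 in Tim4-positive cells (medians -0.02, 0.02 and 0.05). Of its 16 members 0, 2 and 1 rose, Scd2 (3.21 and 2.31 in the Tim4 subsets) and the lysosomal cholesterol transporter Npc1 (0.97, SE 0.17, in Tim4-negative cells), and 1 fell in each subset, Lpl. Abcg1 (-0.16, 0.02 and 0.07) and Apoe (0.08, 0.03 and 0.02) did not pass in any subset. Nor did the exporter Abca1, though its estimates were all negative (-0.12, -0.52 and -0.71, adjusted p = 0.811, 0.276 and 0.0545). From 4 to 8 weeks Abca1 fell past the test in Tim4-negative (-1.03) and Tim4-positive cells (-1.13), but not in CD64+CCR2+ cells (0.11). Apoe lay at 12.70 to 12.96 in the naive and 8 week groups, near the highest value of any array (13.62), where a rise would be hard to see. No difference between subsets passed for the rise of sterol genes (adjusted p = 0.077, 0.15 and 0.95 for the 3 differences), whose medians were 0.43, 0.94 and 0.68. None passed for the IL-4 list either (0.614, 0.349 and 0.876).

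**Figure D4:**
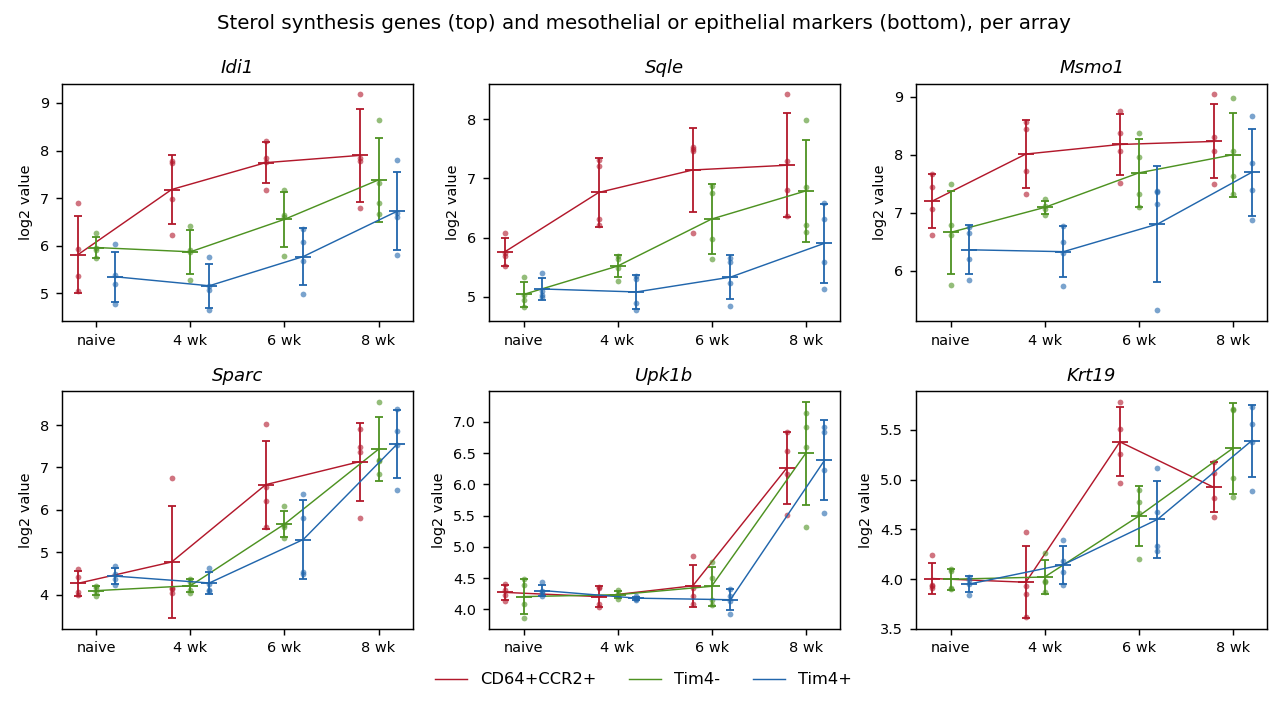
Log2 level (vertical) of 3 sterol synthesis genes (top) and 3 mesothelial or epithelial markers (bottom) in naive mice and 4, 6 and 8 weeks after ID8 injection (horizontal), with points for arrays, bars for the mean and SD of 4 arrays and lines joining the means of each subset. At 8 weeks against naive Upk1b is up by 1.99, 2.29 and 2.08 and Sqle by 1.46 in CD64+CCR2+ and 1.75 in Tim4-negative cells.

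Markers of mesothelium and epithelium, tissues that line the cavity or give rise to the tumour, rose beside these groups at 8 weeks in all 3 subsets. Upk1b rose by 1.99 (SE 0.26), 2.29 (SE 0.26) and 2.08 (SE 0.26) in CD64+CCR2+, Tim4-negative and Tim4-positive cells. In the same order Krt19 rose by 0.92 (SE 0.20), 1.32 (SE 0.20) and 1.44 (SE 0.20), and the matrix gene Dcn by 1.32, 1.31 and 1.30 (SE 0.25 each). Naive levels of Upk1b and Krt19 lay below the array medians (4.64 to 4.96), so rises from them are lower bounds. In CD64+CCR2+ cells Krt19 reached only 4.92 at 8 weeks, so neither of its levels there can be told from background. It reached 5.31 in Tim4-negative and 5.39 in Tim4-positive cells. The mesothelial and fibroblast list, which includes Sparc and Dcn, had 5, 6 and 5 of 13 members up (adjusted p = 8.98e-07, 4.17e-07 and 0.000174, and 0.0534, 0.0373 and 0.118 with an estimated correlation). The epithelial list had 1, 3 and 3 of 11 members up (0.145, 0.000373 and 0.0475; 0.0796 and 0.374 estimated for the latter pair), with means of 0.22, 0.42 and 0.30 but medians of -0.03, 0.01 and 0.05. At 6 weeks the epithelial list passed in CD64+CCR2+ cells (0.00225, and 0.195 estimated; median 0.00, mean 0.31), with Krt19 (1.38, SE 0.20) and Krt18 (1.27) up.

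Of the lists of other blood cells, only the mast cell and dendritic cell markers passed at 8 weeks, each with a fall, in CD64+CCR2+ cells (0.0182 for either) and, for mast cells, in Tim4-negative cells (0.000126). None of these held with an estimated correlation (0.339 and 0.365 for mast and dendritic cell markers in CD64+CCR2+ cells, 0.0763 for mast cell markers in Tim4-negative cells). In the order CD64+CCR2+, Tim4-negative, Tim4-positive, the adjusted p was 0.936, 0.504 and 0.404 for B cells, 0.223, 0.726 and 0.854 for T cells, 0.145, 0.138 and 0.362 for NK cells, and 0.716, 0.235 and 0.404 for neutrophils. It was 0.166, 0.102 and 0.183 for eosinophils and 0.145, 0.145 and 0.586 for erythroid cells, while mast cell markers in Tim4-positive cells had 0.136 and dendritic cell markers 0.872 and 0.474 in the Tim4 subsets. NF-kB genes (0.509, 0.504 and 0.437) and the pro-angiogenic list (0.509, 0.235 and 0.264) did not change either. Fatty acid oxidation had 0.814 and 0.517 in the first 2 subsets.

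**Figure D5:**
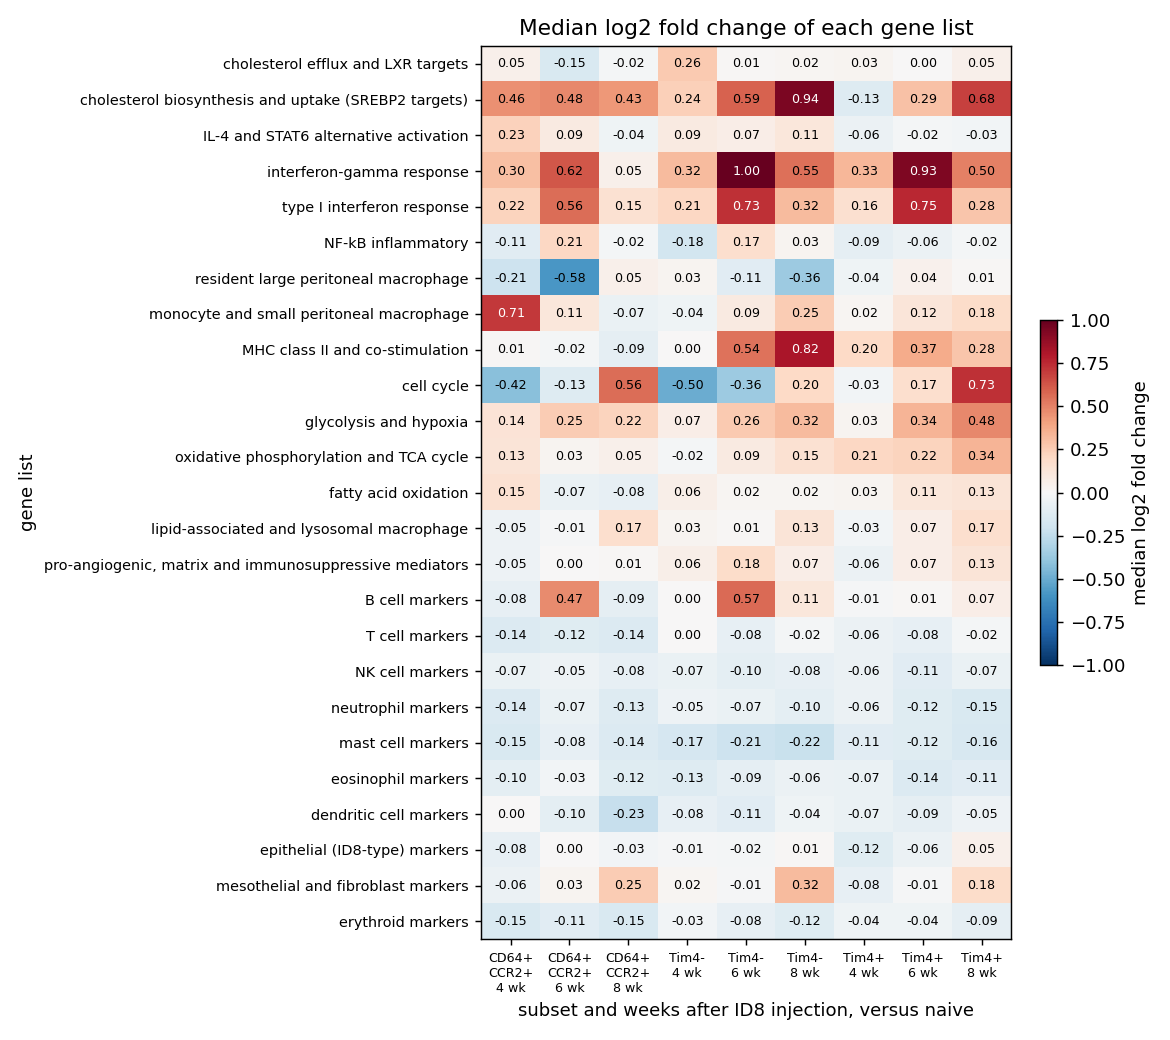
Median log2 fold change against naive (colour and printed value) of the measured members of each of the 25 gene lists (vertical) at 4, 6 and 8 weeks in each subset (horizontal). The interferon-gamma list stands highest at 6 weeks (0.62, 1.00 and 0.93) and the sterol list is positive in all subsets at 8 weeks (0.43, 0.94 and 0.68).

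The 8 week changes of different subsets, which share no arrays, overlapped. The labels do not say whether the subsets were sorted from the same mice, and the values for independent lists given here leave shared mice out. They also leave out a batch that followed the code in the titles, which would move the same genes in every subset. All 19938 genes, dim ones included, were taken as equally likely to pass. Of the genes that rose, 33 were shared by Tim4-positive and Tim4-negative cells, against 0.314 if the lists were independent, 23 by CD64+CCR2+ and Tim4-negative cells (0.271) and 13 by CD64+CCR2+ and Tim4-positive cells (0.327). Sparc and Upk1b were among the genes that rose in all 3 subsets. Of the genes that fell, 4, 4 and 2 were shared in the same order (0.0117, 0.0163 and 0.0117), and 0 changed in opposite directions. Without the arrays with Y-linked transcripts 19, 10 and 15 were shared among genes that rose and 1, 2 and 2 among those that fell, and without the naive arrays numbered 1 these were 31, 18 and 9, and 17, 10 and 8.

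Between 4 and 8 weeks proliferation genes rose in CD64+CCR2+ cells (genes chosen after their values were seen). In CD64+CCR2+ cells Ccna2 (1.83, SE 0.42), Ccne2 (1.48, SE 0.27) and the spindle gene Tpx2 (1.37, SE 0.28) rose, with 8 of 29 cell cycle genes past the test and 22 adjusted over the list alone (median 0.99; adjusted p = 7.82e-27, and 0.0281 with an estimated correlation). The list also passed in Tim4-negative (median 0.77; 2.38e-15, and 0.0977 estimated) and Tim4-positive cells (median 0.70; 3.97e-18, and 0.0894 estimated) with 0 members past the test by limma and 11 and 15 adjusted over the list alone, calls that were lost with the estimated correlation. Monocyte genes fell in CD64+CCR2+ cells (median -0.58; 2.44e-10, and 0.00347 estimated), with Plac8 (-2.81, SE 0.73) and Cd209a (-3.63, SE 0.64) down, and rose in Tim4-negative cells (1.07e-06, and 0.0258 estimated), with Ccr2 (1.97, SE 0.31) and Cx3cr1 (1.68, SE 0.25) up. Abca1 fell in Tim4-negative (-1.03, SE 0.23, adjusted p = 0.0275) and Tim4-positive cells (-1.13, SE 0.23, adjusted p = 0.0107), while sterol genes rose in both (4.03e-14 and 5.45e-11; 0.0658 and 0.139 estimated), with 0 and 1 of 20 members past the test by limma and 10 and 11 adjusted over the list alone. The efflux list fell in Tim4-negative cells (0.0237, and 0.187 estimated), 2 of 16 members down. Mesothelial and fibroblast markers rose as a list in all 3 subsets (9.16e-10, 9.3e-10 and 3.73e-08, and 0.00357, 0.00717 and 0.0223 estimated).

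From 4 to 8 weeks 122 genes passed in CD64+CCR2+ (69 higher, 53 lower), 39 in Tim4-negative (36 and 3) and 30 in Tim4-positive cells (24 and 6). Array weights gave 68 and 84 in the Tim4 subsets, and a fit limited to the groups compared gave 9 in CD64+CCR2+ and 4 in Tim4-positive cells. The CD64+CCR2+ count was 65, 80 and 55 without 4 week array 2 and 8 week arrays 3 and 4, and without 8 week array 4 the other counts were 19 and 18.

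At 8 weeks the subsets still differed in resident and monocyte genes (genes chosen after their values were seen). Timd4 was higher in Tim4-positive than Tim4-negative cells by 6.27 (SE 0.32, adjusted p = 2.46e-17) and Apoc1 by 3.91 (SE 0.58). Ccr2 (-3.84, SE 0.31), Mrc1 (-1.83, SE 0.32, adjusted p = 0.000744), Retnla (-1.45, SE 0.23) and Cd226 (-2.43, SE 0.33) were lower. CD64+CCR2+ cells had less Vsig4 (-3.94, SE 0.55) and Ltbp1 (-3.77, SE 0.22) and more of the lectin Mgl2 (2.53, SE 0.50) than Tim4-negative cells, and more Ccr2 (5.67, SE 0.31) and Mrc1 (2.85, SE 0.32) than Tim4-positive cells. In the order Tim4-positive against Tim4-negative, CD64+CCR2+ against Tim4-negative and CD64+CCR2+ against Tim4-positive, 73 genes (42 higher, 31 lower), 76 (22 and 54) and 338 (162 and 176) passed. With arrays shifted to a common median the last split was 172 higher and 169 lower. Resident genes, which include the sort marker Timd4, differed in every pair, with 6 of 17 higher in Tim4-positive than Tim4-negative cells (8.48e-24, and 0.000835 with an estimated correlation). In CD64+CCR2+ cells 12 and 15 were lower (2.07e-44 and 4.37e-56, and 9.89e-06 and 9.26e-07 estimated). The IL-4 list was lower in Tim4-positive than Tim4-negative cells (0.000714, and 0.041 estimated) and higher in CD64+CCR2+ cells than in either (0.00239 and 2.11e-06; 0.0708 and 0.00351 estimated).

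The genes whose tumour effect at 8 weeks differed between subsets included the surface receptors Fcrls, Cd226 and Slamf9 that were high in naive CD64+CCR2+ cells. The naive level and the tumour effect use the same naive arrays, so noise in these arrays moves both. A difference may also lie in the change of the other subset. As given above, Cd226 rose in Tim4-negative cells, and in Tim4-positive cells Gpnmb rose and Lama3 fell. Relative to Tim4-negative cells, the change in CD64+CCR2+ cells was lower for Fcrls (-2.57, SE 0.56, adjusted p = 0.0389), the leukotriene receptor Ltb4r1 (-2.31, SE 0.48), Cd226 (-2.23, SE 0.47), Slamf9 (-2.19, SE 0.46), Cd209f (-1.79, SE 0.36) and Batf3 (-1.39, SE 0.29). It was higher for the ubiquitin ligase Nedd4 (2.08, SE 0.42), Tlr13 (1.90, SE 0.38), the drug exporter Abcb1b (1.88, SE 0.35), Vbp1 (1.11, SE 0.22), Cnot7 (1.08, SE 0.20) and Kansl1l (1.03, SE 0.22). Relative to Tim4-positive cells it was lower for Cd209f (-1.83, SE 0.36), Ptpn1 (-1.42, SE 0.25), Gpnmb (-1.31, SE 0.26) and Ap2s1 (-1.11, SE 0.23) and higher for Lama3 (1.26, SE 0.26). Arg1 (adjusted p = 0.999, 0.795 and 0.761) and Abca1 (0.991, 0.796 and 0.651) did not pass in any of the 3 differences. For Arg1 the SE was 1.01, so a sizeable difference could be missed. The difference in Mrc1 between CD64+CCR2+ and Tim4-negative cells did not pass either (-1.76, SE 0.46, adjusted p = 0.129).

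Between Tim4-positive and Tim4-negative cells 0 genes differed in tumour effect by limma, with 1087 at unadjusted p under 0.05 (1 gene without Tim4-positive 8 week array 2). Between CD64+CCR2+ and Tim4-negative cells 18 did (6 higher, 12 lower), and between CD64+CCR2+ and Tim4-positive cells 5 (1 and 4). The splits were 5 and 4, and 0 and 3, with a common median. Without the arrays with Y-linked transcripts the counts were 12 and 11, and without the naive arrays numbered 1 they were 3 and 1. With a fit limited to the groups compared they were 2 and 1, and leaving out dim genes gave 3 for the latter. These fits made no use of the replicate number. With the number as a fixed block within time both counts were higher, as given under the processing. All 12 and 5 genes named were lost without CD64+CCR2+ 8 week array 3 or array 4.

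Single arrays moved both counts. For CD64+CCR2+ against Tim4-negative cells the count was 34, 0 and 0 without CD64+CCR2+ 8 week arrays 2, 3 and 4, 7, 10 and 39 without CD64+CCR2+ naive arrays 1, 2 and 4, 11 and 0 without Tim4-negative 8 week arrays 2 and 4, and 6, 11 and 8 without Tim4-negative naive arrays 1, 2 and 3. For CD64+CCR2+ against Tim4-positive cells it was 1, 0 and 0 without CD64+CCR2+ 8 week arrays 2, 3 and 4, 2, 2, 9 and 11 without CD64+CCR2+ naive arrays 1, 2, 3 and 4, 0 and 0 without Tim4-positive 8 week arrays 3 and 4, and 10, 1, 3 and 2 without Tim4-positive naive arrays 1, 2, 3 and 4.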

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

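The tests of the 3 patterns weighed in this part and the counts over other splits of the arrays were chosen only after the results they bear on had been seen, whereas the differences of the tumour effect, by gene and by list, were planned. The Y-linked transcripts in 6 of the 12 naive arrays, weighed first, came with a loss of Xist, which is consistent with naive donors of both sexes. In genes called in the other 2 subsets without these arrays, an array exchanged with a tumour group would lie at the tumour level, but at 6 and 8 weeks the highest median of such an array was 0.06 and the lowest of a tumour array 0.27, which speaks against that exchange. At 4 weeks, with 24 to 34 genes, the values were too close to tell (0.11 against 0.13 in Tim4-negative cells), so an exchange with 4 week arrays stays open. If the sex of the naive mice made the 8 week calls, naive arrays without and with the signal would differ in the direction of the tumour change. The largest median of that difference was 0.12 against median tumour changes of 1.39, 1.32 and 1.29 in CD64+CCR2+, Tim4-negative and Tim4-positive cells. Its 90th percentiles were 0.60, 0.77 and 0.40, so single genes differed more. The fit counts a difference between such naive arrays as spread. A gene changed by sex alone in all subsets would therefore seldom be called, and the median cannot exclude sex in single genes. All 93, 90 and 100 genes kept their direction without the 6 arrays, which was likely in advance, since the tumour arrays and the other naive arrays were the same. Past both thresholds 59, 55 and 65 of them stayed.

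The joint rise of mesothelial, fibroblast and epithelial markers at 8 weeks may come from RNA of tumour or mesothelial cells among the sorted cells, from fibroblasts, or from expression by the macrophages. RNA of another cell type would rise and fall as a unit from array to array. Deviations from the group mean were compared for 9 risen markers (Upk3b, Msln, Wt1, Upk1b, Dcn, Sparc, Krt8, Krt18 and Krt19). In the 12 arrays at 8 weeks their mean correlation was 0.432, above the highest of 1000 random gene sets of like level (0.326). It was 0.085 in naive arrays, where Sparc, Upk1b and Krt19 lay below the array medians, so that low value says nothing about the cause. Carried-over tumour or mesothelial RNA would give the 0.432. Macrophages that differ between samples in expressing these genes, or any genes regulated together, would give the same pattern. Arrays of the same number may share a sample, which the random sets leave out. Fibroblast RNA would bring collagens with it, and the largest median change of Col1a1, Col1a2 and Col3a1 was -0.04, which does not favour it, although Dcn (1.32, 1.31 and 1.30) and Sparc (2.87, 3.33 and 3.11), which fibroblasts also express, rose.

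The rise of sterol synthesis genes at 8 weeks may be a response of the macrophages, a trace of the naive arrays with Y-linked transcripts, carried-over tumour RNA, or a batch that follows the code in the titles. With a term for the Y-linked signal the subset medians were 0.43, 0.83 and 0.50, against 0.43, 0.94 and 0.68 without it, so those arrays do not account for the whole rise, although the medians of Tim4-negative and Tim4-positive cells were lower with the term. In CD64+CCR2+ cells the list already had a median change of 0.46 at 4 weeks, when the markers that later rose had a median of -0.06 (highest 0.51), which speaks against carried-over tumour RNA for that part alone, a part whose call is lost with an estimated correlation (0.522), with 0 of 20 members past the test by limma, in a comparison where chance cannot be excluded. The code in the titles cannot be told apart from tumour time, and the test that could have separated them, a difference of the rise between subsets, gave a lowest adjusted p of 0.077. At 8 weeks array 2 had the highest list median in every subset (1.34, 1.77 and 1.36, the others at most 0.48, 0.89 and 0.49), so a state of that sample or its handling stays open as a part of the rise, and the test of differences made no use of the array numbers.

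Of 156 groups of 4 arrays tested for a focal gene, 8 had a single array apart from the other 3 by Dixon's ratio, where chance alone gives about 1 in 20. In Timd4 these were array 4 of Tim4-negative cells at 8 weeks (6.08, the others 4.64 to 4.87) and array 3 of Tim4-positive cells at 6 weeks (11.75, the others 11.37 to 11.42). In Ccr2 it was array 2 of naive Tim4-negative cells (9.57, the others 8.77 to 8.88), and in Abcg1 array 1 of naive CD64+CCR2+ cells (8.25, the others 6.73 to 6.84). In Arg1 it was array 3 of naive Tim4-positive cells (9.64, the others 8.71 to 8.84), and in Mrc1 array 2 of Tim4-positive cells at 6 weeks (7.52, the others 5.62 to 5.80). In Gata6 it was array 4 of Tim4-negative cells at 4 weeks (8.18, the others 8.22 to 8.23), and in Mki67 array 1 of naive Tim4-positive cells (5.37, the others 6.42 to 6.61).

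The tumour effect differed between CD64+CCR2+ and Tim4-negative cells in 18 genes. The named ones were Nedd4 (2.08), Tlr13 (1.90), Abcb1b (1.88), Vbp1 (1.11), Cnot7 (1.08), Kansl1l (1.03), Fcrls (-2.57), Ltb4r1 (-2.31), Cd226 (-2.23), Slamf9 (-2.19), Cd209f (-1.79) and Batf3 (-1.39), in log2 units. Between CD64+CCR2+ and Tim4-positive cells it differed in 5 genes, Lama3 (1.26), Cd209f (-1.83), Ptpn1 (-1.42), Gpnmb (-1.31) and Ap2s1 (-1.11), in the same units. For splits of these arrays the effects of subset and time were first taken out, so that a split moves no difference between subsets into the tumour effect. The splits took no account of the replicate number. Of 100 splits the real ones alone, 1 of 100 each, gave as many as 18 and 5 genes, and the highest others gave 8 and 4, so chance is not favoured for these counts, which single arrays still move. Between Tim4-positive and Tim4-negative cells the count was 0 by limma, with 1087 at unadjusted p under 0.05, and since all 100 splits reach a count of 0 (the highest gave 4) the splits say nothing there.

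By gene list, 14 of 75 differences of the tumour effect had an adjusted p under 0.05, and 0 with an estimated correlation. Between Tim4-positive and Tim4-negative cells these were resident macrophage genes (0.00218), cell cycle (1.67e-06), glycolysis (0.00826) and oxidative phosphorylation (0.00218). Between CD64+CCR2+ and Tim4-negative cells they were the interferon-gamma response (0.0281), resident macrophage genes (0.0128), monocyte genes (0.000943), MHC class II (0.00393), cell cycle (0.00108) and dendritic cell markers (0.0372). Between CD64+CCR2+ and Tim4-positive cells they were monocyte genes (0.0342), MHC class II (0.0011), glycolysis (0.0129) and oxidative phosphorylation (0.000136).

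For the comparisons of 2 groups, the 35 ways to divide the same 8 arrays show how many genes chance division gives. The real division gave the most genes, 1 of 35, in every such comparison except CD64+CCR2+ cells at 4 weeks, so chance is not favoured there. A share of 1 of 35 is the lowest that these divisions can give. Pairs of subsets were made different by the sort, so their real division was likely to lead in advance. Comparisons with naive share the naive arrays of a subset, and the Tim4-negative and Tim4-positive counts at 4 weeks, 5 and 3, moved with single arrays. The highest other count was 52 and 18 for CD64+CCR2+ cells at 6 and 8 weeks, 1, 5 and 1 for Tim4-negative and 1, 45 and 20 for Tim4-positive cells at 4, 6 and 8 weeks. It was 4, 31 and 73 for the naive pairs, 1, 1 and 4 for the pairs at 8 weeks, and 24, 3 and 3 for 8 against 4 weeks. For CD64+CCR2+ cells at 4 weeks 6 of 35 divisions gave 25 genes or more, up to 184 when naive array 1 was placed with the 4 week arrays, so chance cannot be excluded there.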

How the results depend on the processing

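Leaving out the arrays with Y-linked transcripts, the term for them and leaving out the naive arrays numbered 1 were chosen only after the results had been seen, and the other settings before the data were examined. No named gene value reversed in the settings it was run under, 13 settings and each of the 48 arrays left out in turn, of which the fixed block within time covered 205 of 348 named gene values. Splits of counts could turn. With a common median, 6 higher and 12 lower became 5 and 4 in the difference of CD64+CCR2+ from Tim4-negative cells. In CD64+CCR2+ against Tim4-positive cells at 8 weeks, 162 and 176 became 172 and 169. Gene lists were run under 7 settings only (an estimated correlation, dim genes left out, quantile normalization, the random block, and the 3 settings for naive arrays), and none reversed in these. Sign changes of values that were uncalled both ways were counted as the same. Of 254 named gene values past the test, the number that lost their call was 128 with a fit limited to the groups compared, 113 when some single array was left out, 89 without the arrays with Y-linked transcripts, 71 without the naive arrays numbered 1, 38 with array weights, 31 with quantile normalization, 23 with a common median, 18 with a term for Y-linked transcripts, 6 with a trended and robust prior and 1 with averaged probe sets. Leaving out 8033 dim genes ended 5 of these calls. At 8 weeks against naive, 27 of 30, 18 of 37 and 32 of 41 calls in CD64+CCR2+, Tim4-negative and Tim4-positive cells were lost in at least 1 setting. For the naive pairs these were 14 of 19, 23 of 50 and 18 of 60, and for the differences of CD64+CCR2+ cells 12 of 12 and 5 of 5. The shift of the all-gene median under another scaling was never over 0.099, but a median does not show differences in spread. The SD over probe sets was 2.034 to 2.122 in naive Tim4-positive arrays and 2.122 to 2.189 at 8 weeks. In that comparison quantile normalization ended 17 of 41 named calls. Of 525 list tests 133 lost their call with an estimated correlation, 38 without the arrays with Y-linked transcripts and 33 with quantile normalization. With 4 arrays per group, a simulated change of log2 0.50 had an adjusted p under 0.05 in 41 of 67 genes and passed both thresholds in 0, and a change of 1 passed both in 35 of 67. These genes were drawn from all genes, dim ones included, with independent noise, so the shares do not hold for genes of larger SE.

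Counts of genes moved by more than 1.5 times as follows, and the cause was not tested unless given. A fit limited to the groups compared has fewer residual degrees of freedom by construction. It gave 2 for 25, 28 for 128 and 9 for 93 in CD64+CCR2+ cells at 4, 6 and 8 weeks, 2 for 5 and 3 for 81 in Tim4-negative cells at 4 and 6 weeks, and 0 for 3, 5 for 100 and 41 for 100 in Tim4-positive cells. It gave 20 for 56 in naive Tim4-positive against Tim4-negative cells, 232 for 364 in naive CD64+CCR2+ against Tim4-negative cells, 2 for 18 and 1 for 5 in the differences of CD64+CCR2+ cells from Tim4-negative and Tim4-positive cells, and 9 for 122 and 4 for 30 in CD64+CCR2+ and Tim4-positive cells from 4 to 8 weeks. Array weights gave 50 for 25 and 19 for 5 at 4 weeks in CD64+CCR2+ and Tim4-negative cells, 36 for 56 in naive Tim4-positive against Tim4-negative cells, and 68 for 39 and 84 for 30 in the Tim4 subsets from 4 to 8 weeks. Quantile normalization gave 16 for 25 in CD64+CCR2+ cells at 4 weeks. A common median gave 3 for 5 in Tim4-negative cells at 4 weeks, and 9 for 18 and 3 for 5 in the differences of CD64+CCR2+ cells. The trended and robust prior gave 6 for 3 in Tim4-positive cells at 4 weeks, and leaving out dim genes 3 for 5 in the difference of CD64+CCR2+ from Tim4-positive cells.

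Without the arrays with Y-linked transcripts, which leaves 2 naive arrays per subset, the count was 144 for 93 in CD64+CCR2+ cells at 8 weeks, 8 for 5 and 16 for 3 in Tim4-negative and Tim4-positive cells at 4 weeks, and 11 for 5 in the difference of CD64+CCR2+ from Tim4-positive cells. A term for those transcripts gave 143 for 93 and 13 for 3 in CD64+CCR2+ cells at 8 weeks and Tim4-positive cells at 4 weeks. Without the naive arrays numbered 1 it was 98 for 25, 16 for 5 and 18 for 3 at 4 weeks in CD64+CCR2+, Tim4-negative and Tim4-positive cells, and 3 for 18 and 1 for 5 in the differences of CD64+CCR2+ cells.

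The arrays share replicate numbers, which the labels do not tie to mice. Of 48 pairs of arrays with the same number at the same time, the correlation of deviations from the group mean had a median of 0.163 (from -0.147 to 0.601), 30 were over 0.1, and in 37 the array with the same number was the closest of its group. By time, 2 of 12 were over 0.1 at 4 weeks, 11 of 12 at 6 weeks, 11 of 12 at 8 weeks and 6 of 12 in naive mice, and the same number was the closest in 5, 12, 12 and 8. Not every correlation was over 0.1, so the number was left out of the main fit, the differences of the tumour effect included. The match at 6 and 8 weeks hints at shared samples, which the main fit does not use. So does the Y-linked signal, found in naive arrays 2 and 3 of every subset. The block values that follow are therefore given beside the main fit. With the number as a fixed replicate block across groups the count was 6 for 3 in Tim4-positive cells at 4 weeks and 2 for 5 in the difference of CD64+CCR2+ from Tim4-positive cells. With a random replicate block within time these were 5 and 9, at a consensus correlation of 0.06. A fixed replicate block within time gave 100 for 56 in naive Tim4-positive against Tim4-negative cells, and 38 for 18 and 24 for 5 in the differences of CD64+CCR2+ cells.

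With each array left out in turn, the lowest and highest counts at 4, 6 and 8 weeks against naive were 12 and 90, 98 and 162, and 59 and 119 in CD64+CCR2+ cells, 0 and 10, 52 and 108, and 50 and 93 in Tim4-negative cells, and 2 and 11, 48 and 168, and 51 and 156 in Tim4-positive cells. For Tim4-positive against Tim4-negative, CD64+CCR2+ against Tim4-negative and CD64+CCR2+ against Tim4-positive cells they were 38 and 67, 283 and 400, and 489 and 592 in naive mice, 50 and 80, 54 and 79, and 313 and 353 at 8 weeks, and 0 and 1, 0 and 39, and 0 and 11 for the differences of the tumour effect. From 4 to 8 weeks they were 55 and 172, 19 and 38, and 18 and 41 in CD64+CCR2+, Tim4-negative and Tim4-positive cells.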

Other observations

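No test in this part was chosen after its result was seen, and the genes below were named by the rule for naive mice. Several genes from the lists of other cell types separated the naive macrophage subsets. The adhesion gene Cd2, better known from T cells, was higher in CD64+CCR2+ cells than in Tim4-negative cells by 3.22 (SE 0.46) and than in Tim4-positive cells by 3.46 (SE 0.46). Hdc, the enzyme that makes histamine and a mast cell marker, was lower in CD64+CCR2+ cells by -1.70 and -2.49 against the same subsets. Batf3, a transcription factor of dendritic cells, was higher by 1.88 (SE 0.20) and 2.08 (SE 0.20).

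Some members of the lipid, hypoxia and fatty acid oxidation lists differed between naive subsets as well. Against Tim4-negative cells, CD64+CCR2+ cells had lower Fabp5 (-2.30), Cd9 (-3.54, SE 0.43) and Egln3 (-3.26, SE 0.41), the last a prolyl hydroxylase that hypoxia induces. Against Tim4-positive cells they had higher Cpt1a (0.69, SE 0.15), which brings fatty acids into mitochondria. The lipid-associated list did not differ between CD64+CCR2+ and Tim4-negative cells (adjusted p = 0.128; median 0.01, mean -0.42), with 2 of 20 members higher and 4 lower.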
